A study of Mus musculus with 4 samples.

How the data were processed

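Gene expression was measured in semilunar (aortic and pulmonary) valve leaflets of newborn mice on 4 Affymetrix Mouse430_2 arrays. Each array held RNA from a pool of 3 neonates. The pools were 2 of Cxcr7-/- neonates and 2 of control neonates, which the labels describe as wildtype littermates, and the labels call the pools biological replicates. Per the labels, 50 ng of total RNA went through 2 rounds of amplification before hybridisation.

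The deposited values are intensity values on a linear scale, 1 signal per probe set and array. The submitters' processing notes name Affymetrix Expression Console and MAS5, which summarises each probe set from perfect-match and mismatch probes. Software versions, detection calls and a genome build are not given in the sources used here. All 4 arrays had a trimmed mean of 500.003 over the middle 96% of probe sets, as scaling each array to a target of 500 gives. MAS5 subtracts a local background, so dim probe sets carry large relative errors, and a scaling by the mean moves each gene relative to the total signal of its array. A second round of amplification shortens the product and lowers signal from probes far from the 3' end of a transcript. With arrays, their number limits the precision: 2 pools per genotype leave 2 residual degrees of freedom.

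The table held 45101 probe sets. The 64 AFFX control probe sets were set aside for quality values, which left 45037. Signals were taken as log2(signal + 22), where 22 was the 25th percentile of all non-control values rounded to a whole number, and no further normalization was applied. Probe sets with a mean log2 value over the 4 arrays above the median of all non-control probe sets were kept, which gave 22518. Genes were taken from an annotation table of the array by gene identifier: 34945 probe sets had 1 gene symbol, 932 had several and 9160 had none. For gene lists, each gene was represented by the single-symbol probe set with the highest mean, which gave 11260 genes. Positions on the genome were not printed, since the probe sets were joined to genes by identifier and no alignment was made. Cxcr7 is listed under its current symbol, Ackr3. The listed erythroid gene Ahsp was not matched and was left out.

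Genotypes were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with an intensity trend, two-sided), with Benjamini-Hochberg adjustment over the probe sets kept and a threshold of 0.05. Log2 fold changes are Cxcr7-/- minus control and are followed by the standard error of the model, and signals are given for each pool. The model added 5.85 prior degrees of freedom to the 2 residual ones. A count with no test was made beside it of probe sets whose signals differed at least 2-fold in all 4 cross comparisons of a Cxcr7-/- array with a control array. An exact two-sided permutation test of 1 value between 2 and 2 arrays cannot give a p below 0.333, so none was used. Replicate numbers were not tied to a litter or a day by any label, so the arrays were not paired.

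In all, 27 gene lists with at least 5 measured genes were tested with limma's camera at a preset inter-gene correlation of 0.01, with adjustment over the lists. Camera with an estimated correlation and fry were run beside it. Sex-linked genes were given as values. The named genes followed a rule: Cxcr7 itself; up to 12 genes in each direction at least 2-fold apart on average with both Cxcr7-/- arrays on the same side of both control arrays, ranked by unadjusted p; up to 4 members of each list that passed; up to 3 members of the lists on the CXCL12 axis, EGF family, ADAMTS and proteoglycans, Notch, BMP and TGF-beta, and endothelial markers; and Hbegf and Adamts1, which the study is known to have named. Any other gene named in the text was chosen after its values were seen. The lists, the naming rule, the tests and most alternatives were fixed before the data were examined.

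The procedure was tested on 60 simulated data sets with 200 changed probe sets each. Their variances were drawn from the distribution that limma fitted to the data. Their errors were independent and normal, as the test assumes, so the rates may be better than in real data. The procedure called 0.672% of probe sets changed 2-fold, 33.8% of those changed 4-fold and 76.0% of those changed 8-fold. It made 77.7 calls and 4.52 false calls per data set on average. For lists, genes were drawn independently and a single list was judged at an unadjusted p under 0.05. A list shifted by 0.60 log2 was then called in 100% of runs with the preset correlation and in 98.3% with an estimated one. A list with both a shift and correlated genes was not simulated, so these rates do not carry over to the real lists, adjusted over 27. A list whose genes shared a random shift per pool (SD 0.40 log2) and no genotype effect was called in 76.7% of runs with the preset correlation and in 3.33% with an estimated one.

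The alternatives tried were no pseudocount and one 4 times larger, no filter on dim probe sets and one at the 75th percentile, quantile normalization, median centring, a variance model without trend or with robust estimation, the replicate number as a block, other thresholds, other choices of probe set, other list tests, and leaving out each array in turn. With an array left out, the lone array of that genotype was assumed to vary like the other genotype. A crossed pairing of the arrays, adjustment over 1 probe set per gene or over the list genes alone, the other ways to part the arrays, and 6 further gene lists were chosen after seeing the data.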

Results

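The data described the transcriptome of aortic and pulmonary valve leaflets from newborn mice that lacked Cxcr7 (Ackr3), a receptor that binds and scavenges the chemokine CXCL12, and from wildtype littermates. The question was how valve gene expression differs when the receptor is absent, in a series titled for the semilunar valve phenotype. There were 2 pools per genotype, each of 3 neonates on 1 array. The median signal was 84.5 and 92.5 in the Cxcr7-/- pools and 110 and 89.9 in the control pools. Over the 22518 probe sets kept, the Cxcr7-/- pools correlated with each other at r = 0.956 and the control pools at r = 0.931. Cxcr7-/- replicate 2 and control replicate 1 correlated at r = 0.953, so pools of different genotype were in this case closer than the control pools were to each other. These correlations run across probe sets, which are not independent replicates.

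Cxcr7 itself had the largest difference of the named genes. Its signal was 28.3 and 328 in the Cxcr7-/- pools and 4936 and 5698 in the control pools, which put the mutant pools at 0.532% and 6.18% of the control mean. The log2 fold change was -5.33 ± 0.76 (SE, n = 2 and 2 pools). Whether the signal in Cxcr7-/- replicate 2 is residual transcript, binding of another transcript or carried RNA was not determined. The mutant pools also differed from each other by a large factor at low signal, and the adjusted p from limma was 0.400. The size of the fold change depends on the pseudocount, since 28.3 is close to 22: it was -5.78 with none and -4.61 with one 4 times larger. With 1 array left out it was -6.73 without Cxcr7-/- replicate 2 (adjusted p = 0.000111), -5.43 without control replicate 1 (0.0112), -3.93 without Cxcr7-/- replicate 1 (0.0586) and -5.22 without control replicate 2 (0.121).

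Among the genes with lower signal in Cxcr7-/- leaflets, claudin 5 (Cldn5), a tight junction protein of endothelial cells, read 1131 and 1029 in the mutant pools against 3172 and 4126 in the control pools, a log2 fold change of -1.73 ± 0.26. Hbegf, which encodes the heparin-binding ligand of the EGF receptor, read 616 and 662 against 1984 and 2283 (-1.70 ± 0.26), and its other kept probe set had the same sign at -0.73 ± 0.27. Prg4, which encodes the lubricating proteoglycan lubricin, read 776 and 1059 against 3274 and 2844 (-1.73 ± 0.27). On the other side, the mannose receptor Mrc1 of resident macrophages read 1908 and 1820 against 618 and 466 (1.75 ± 0.28), and Wif1, a secreted Wnt inhibitor, read 10222 and 8640 against 3940 and 1811 (1.81 ± 0.36). No probe set passed the adjusted threshold of 0.05 in limma (smallest adjusted p 0.400), so these are given as values and not as changes.

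The other genes with lower signal and the smallest unadjusted p were Cux2 at -2.75, Scgb1a1 at -2.78, Scgb3a2 at -2.37, Coch at -2.29, H3f3b at -2.27, Thsd7a at -2.23, Mid1 at -1.91 and Ypel2 at -1.35 on the log2 scale. Scgb1a1 and Scgb3a2 encode secretoglobins of airway epithelium (Scgb1a1 read 23.4 and 55.5 in the Cxcr7-/- pools, near the pseudocount), and Coch encodes the extracellular matrix protein cochlin. The other kept probe set of Cux2 had the opposite sign, at 0.11 ± 0.37. Higher signal was seen for H2-Eb1, an MHC class II chain, at 1.84, for Prph, a neuronal intermediate filament, at 1.77, and for Opcml at 1.70 and Tmem100 at 1.66. Ociad2 (1.54), Chn2 (1.49), Kif20a (1.42), Npnt (1.40), Serpinb1a (1.25) and Anln (1.21) followed. Npnt encodes the matrix protein nephronectin, and Kif20a and Anln encode proteins of cytokinesis.

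**Figure D1:**
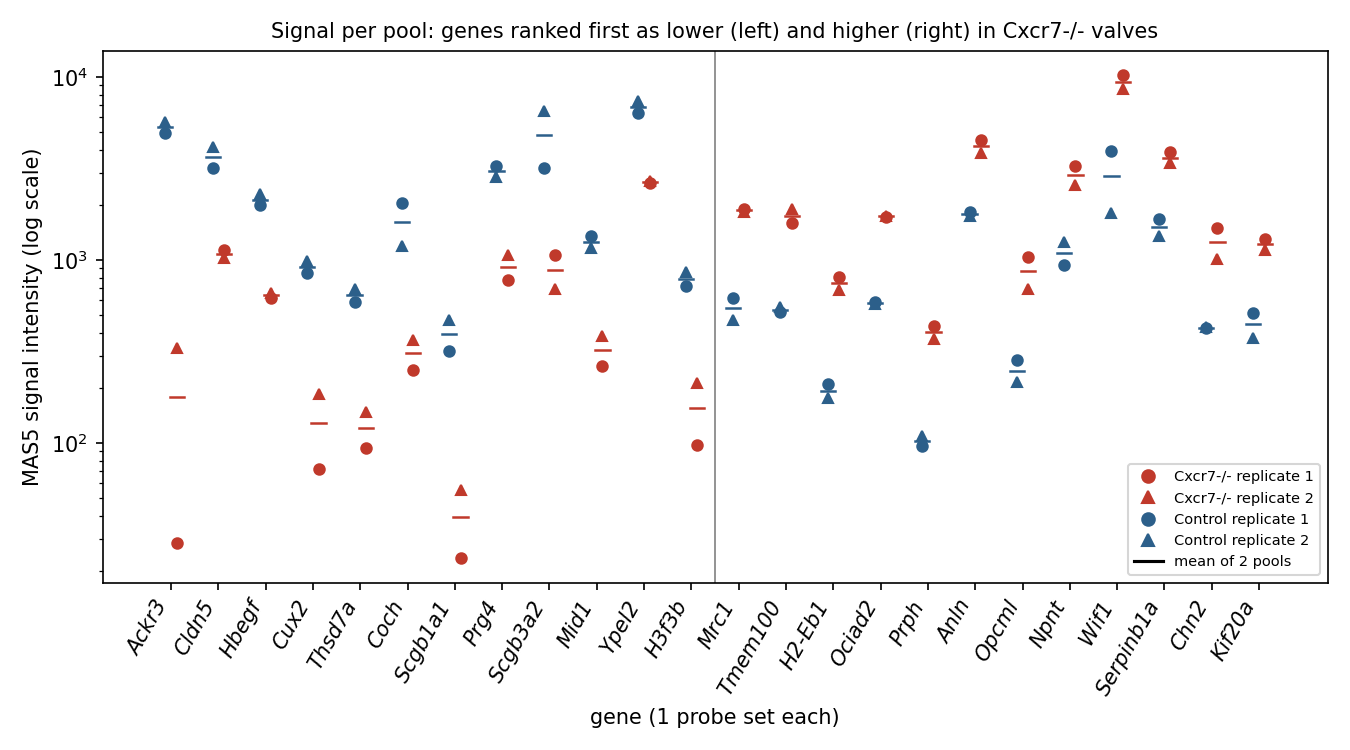
Signal of named genes in each of the 4 pools on a log axis, with 1 point per pool, a short bar for the mean of 2 pools, and the genotypes in different colours. Cxcr7 separates the genotypes most, with 28.3 and 328 in the Cxcr7-/- pools against 4936 and 5698 in the control pools, and Mrc1 lies higher in the Cxcr7-/- pools, at 1908 and 1820 against 618 and 466.

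At an unadjusted p under 0.05 there were 2279 probe sets, 888 higher and 1391 lower in Cxcr7-/- pools, where 1126 were expected by chance. Probe sets are not independent, which leaves that expected count as it is and widens the spread around it. The same count was 183 for both replicates 1 against both replicates 2. It was 1190 for Cxcr7-/- replicate 1 with control replicate 2 against the other arrays. At least 2-fold apart in all 4 cross comparisons were 240 probe sets, 66 higher and 174 lower. The count past the adjusted threshold rested on single arrays: it was 0 with all arrays, 673 without control replicate 1 and 8 without Cxcr7-/- replicate 2. The median standard error of a log2 fold change was 0.34, as large as the median absolute log2 fold change of 0.31.

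Cell cycle genes were higher in both Cxcr7-/- pools. Of 39 measured cell cycle genes, 35 had positive log2 fold changes, 17 of them at an unadjusted p under 0.05, and the median was 0.67. Adjusted over the list alone, 11 genes rose, among them the cytokinesis kinesin Kif20a at 1.42 ± 0.30, the mitotic checkpoint kinase Bub1 at 1.22 ± 0.29, the spindle factor Tpx2 at 1.16 ± 0.28 and the replication clamp Pcna at 0.83 ± 0.22. Over all probe sets tested none did, for this or any other list. Over the 536 genes of all lists together 3 passed, Cldn5, Hbegf and Mrc1, so every other gene said to have risen or fallen did so adjusted over its list alone and not over all lists. The list passed with the preset correlation at adjusted p = 2.5e-14, and gave adjusted p = 0.713 with an estimated correlation. By fry in 1 direction the adjusted p was 0.210. For this and the other lists, the p with the preset correlation reflects spread over genes, not over the 2 pools per genotype.

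Macrophage markers were higher in both Cxcr7-/- pools as well. All 27 measured genes had positive log2 fold changes, 12 at an unadjusted p under 0.05, with a median of 0.71. Adjusted over the list alone, 3 rose: Mrc1, the coagulation factor XIII subunit F13a1 at 1.43 ± 0.32 and the lysosomal glycoprotein Cd68 at 1.55 ± 0.38. The membrane protein gene Ms4a7 was at 1.15 ± 0.34. The list passed at adjusted p = 1.13e-13 with the preset correlation, and gave adjusted p = 0.713 with an estimated correlation.

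Interferon-stimulated genes had a median of 0.55, with 18 of 23 positive and 6 at an unadjusted p under 0.05, and none passed adjusted over the list alone. Irf9, a subunit of the interferon-activated transcription complex, was at 1.01 ± 0.30, Oasl2 at 0.98 ± 0.32, Ifit1 at 0.96 ± 0.32 and the GTPase Iigp1 at 0.68 ± 0.25. The list passed at adjusted p = 0.000151 and gave adjusted p = 0.713 with an estimated correlation, and without Cxcr7-/- replicate 1 its median was 0.28 at adjusted p = 0.0842. Neuronal and Schwann cell markers had a median of 0.44, with 7 of 10 positive and 3 at an unadjusted p under 0.05. Prph rose adjusted over the list alone, at 1.77 ± 0.34. The neuronal tubulin Tubb3 was at 1.10 ± 0.33 and Stmn2 at 0.88 ± 0.33, while Gap43, a growth cone protein, was at 0.40 ± 0.29. The list passed at adjusted p = 0.0212 and gave adjusted p = 0.713 with an estimated correlation. Its median was 0.57 without Cxcr7-/- replicate 2 (adjusted p = 0.0535), 0.31 without control replicate 1 (adjusted p = 0.0979) and 0.23 without control replicate 2 (adjusted p = 0.0472).

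Cardiomyocyte markers were lower in Cxcr7-/- pools. All 29 measured genes had negative log2 fold changes, 14 at an unadjusted p under 0.05, with a median of -0.88. Adjusted over the list alone, 6 fell, among them the alpha myosin heavy chain Myh6 at -1.54 ± 0.34, cardiac troponin I (Tnni3) at -1.55 ± 0.38, the muscle cytochrome oxidase subunit Cox6a2 at -1.82 ± 0.43 and myoglobin (Mb) at -1.67 ± 0.44. The list passed at adjusted p = 4.2e-15 and gave adjusted p = 0.713 with an estimated correlation. The amount also differed between pools of 1 genotype: the median member difference was 0.97 between control replicates 2 and 1 and 0.63 between Cxcr7-/- replicates 2 and 1. The median was -0.51 without control replicate 2, -0.51 without Cxcr7-/- replicate 1, -1.30 without Cxcr7-/- replicate 2 and -1.24 without control replicate 1. Without control replicate 2, Cox6a2 was at -1.16, Tnni3 at -0.99 and Mb at -0.92.

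Smooth muscle markers had a median of -0.57, with 15 of 17 negative, 6 lower and 1 higher at an unadjusted p under 0.05, and none adjusted over the list alone. Myocd, the coactivator of smooth and cardiac muscle genes, was at -1.70 ± 0.47, desmin (Des) at -1.32 ± 0.47, Myl9 at -0.84 ± 0.28 and Tagln at -0.71 ± 0.24. Single pools weigh on the first of these: Myocd read 166 and 494 in the Cxcr7-/- pools against 872 and 1121, and Des 138 and 196 against 278 and 708. The list passed at adjusted p = 0.000113 and gave adjusted p = 0.713 with an estimated correlation. It shares the gene Pln with the cardiomyocyte list, and carried myocardium was not told apart from smooth muscle. All 5 measured adipocyte markers were negative, with a median of -0.89 (adjusted p = 0.00149, and adjusted p = 0.713 with an estimated correlation). Adjusted over the list alone 2 fell, Cox8b at -2.36 ± 0.56 and lipoprotein lipase (Lpl) at -1.35 ± 0.32, both of which are also expressed in heart muscle. Cox8b read 11.4 and 62.7 in the Cxcr7-/- pools, near the pseudocount of 22, so the size of its fold change is uncertain, and Lpl was at -0.89 without Cxcr7-/- replicate 1. Fabp4 was at -0.65 ± 0.34 and Plin4 at -0.89 ± 0.76, and the genotypes overlapped for both. Fabp4 read 1381 and 2357 in the Cxcr7-/- pools against 3483 and 2307, and Plin4 read 59.2 and 98.5 against 54.4 and 418. The adipocyte median was -1.48 without control replicate 1, -0.94 without control replicate 2 and -0.61 without Cxcr7-/- replicate 1. It covers 5 of the 20 listed genes.

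**Figure D2:**
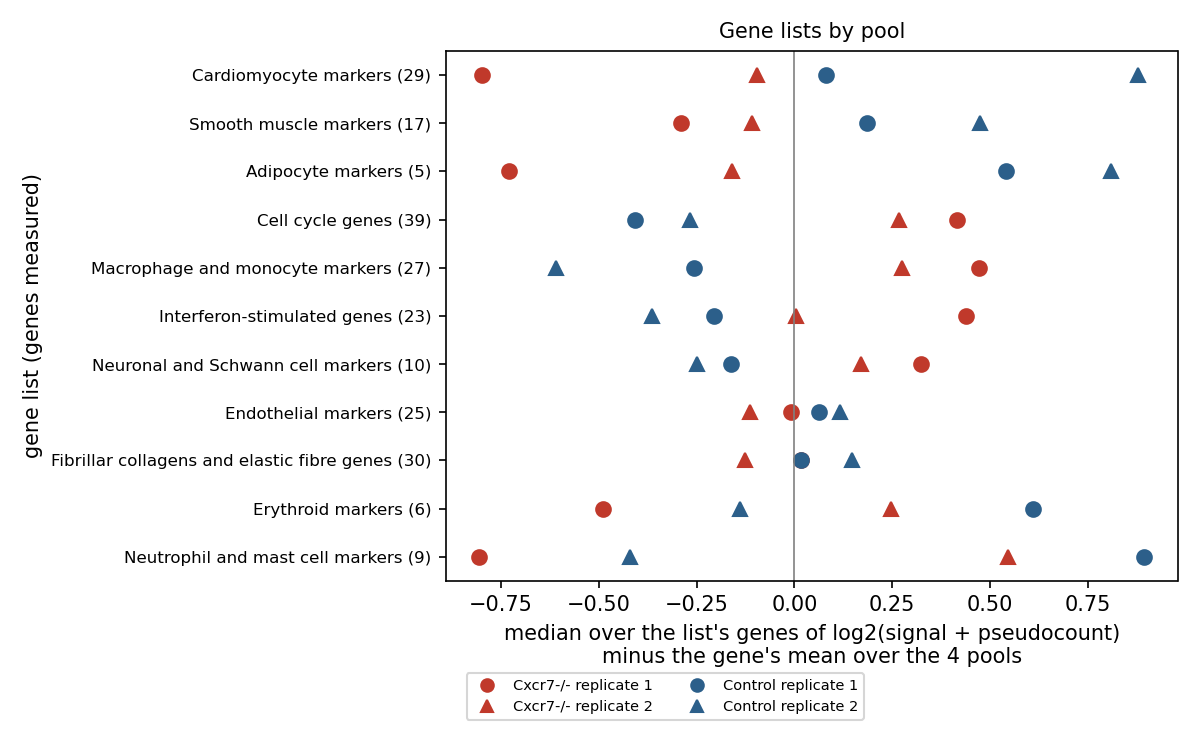
Median over the genes of each list of the log2 signal minus the gene's mean over the 4 pools, with 1 point per pool, colour for genotype and shape for replicate number. Cell cycle genes lie at 0.42 and 0.27 in the Cxcr7-/- pools and at -0.41 and -0.27 in the control pools, while cardiomyocyte markers spread from 0.08 to 0.88 between the control pools.

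Array quality values differed between the pools. The ratio of 3' to 5' signal of the Actb control probe sets was 15.5 and 11.7 in the Cxcr7-/- pools and 20.2 and 19.1 in the control pools. The Gapdh ratio was 12.6 and 8.20 against 12.7 and 24.2. Control replicate 2 stood apart from the other arrays: the 3' probe set of the dap spike read 2487 there and 9047, 7291 and 12669.5 in Cxcr7-/- replicates 1 and 2 and control replicate 1, and that of the cre hybridisation control read 32444 against 54293, 63525 and 74535. Its score on the first principal component was 64.9, against -36.4, -34.9 and 6.42. Neutrophil and mast cell markers (median -0.34, adjusted p = 0.730) and erythroid markers (-0.30, adjusted p = 0.279) did not pass. Lymphatic endothelial markers (0.07) and melanocyte markers (0.10), each at adjusted p = 0.925, did not pass either. The lymphocyte list had 3 measured genes, too few for a test.

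Endothelial markers did not pass as a list (median -0.10, mean -0.26, adjusted p = 0.0873). Of 25 genes, 5 were lower and 0 higher at an unadjusted p under 0.05, and Cldn5 fell adjusted over the list alone. Vwf, which encodes the von Willebrand factor, was at -0.83 ± 0.24, and Robo4, an endothelial guidance receptor, was at -1.24 ± 0.41. Among shear-responsive endothelial genes (median -0.07, adjusted p = 0.925), the gap junction gene Gja4 fell (-1.48 ± 0.26) and the water channel gene Aqp1 rose (1.29 ± 0.27), both adjusted over the list alone. Over the 536 genes of all lists together they did not pass, at adjusted p = 0.0608 and 0.0872.

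The EGF family list did not pass (median 0.09, adjusted p = 0.925). Hbegf was the 1 gene of 16 to pass adjusted over the list alone. The study is known to have named Hbegf, so it is not independent evidence here. Nrg1, a ligand of ErbB receptors, was at 1.09 ± 0.35 and the sheddase regulator Rhbdf1 at -0.76 ± 0.29. Output genes of the ERK pathway had a median of 0.24 (14 genes, adjusted p = 0.202), with 1 at an unadjusted p under 0.05.

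Matrix genes went in both directions. Of 25 measured ADAMTS, proteoglycan and hyaluronan genes (median 0.20, mean 0.03, adjusted p = 0.302), the small leucine-rich proteoglycan genes Fmod at -0.92 ± 0.23 and Ogn at -2.11 ± 0.52 fell adjusted over the list alone, and the hyaluronan link protein gene Hapln1 rose, at 0.97 ± 0.23. All 6 kept probe sets of Fmod were lower. Ogn read 338 and 1243 against 3085 and 2692, and was at -1.20 without Cxcr7-/- replicate 1. Adamts1, a protease that cuts versican and was also named by the study, read 3571 and 2965 against 2158 and 1773, a log2 fold change of 0.73 ± 0.25 (adjusted p = 0.447), and is not independent evidence. In the list of fibrillar collagens and elastic fibre genes (30 genes, median -0.03, or 0.024 after median centring, adjusted p = 0.106), elastin (Eln) fell adjusted over the list alone, with 3250 and 3648 against 8101 and 8029 (-1.22 ± 0.22), and its other probe set was at -2.24 ± 0.51. Metalloproteinases and inhibitors had a median of -0.10 and a mean of 0.14 (adjusted p = 0.666). Among cartilage, tendon and bone genes (median -0.15, adjusted p = 0.999), the collagen IX gene Col9a1 rose adjusted over the list alone, at 1.12 ± 0.25.

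Genes of the CXCL12 axis other than Cxcr7, which was not in the list, did not pass (14 genes, median 0.19, adjusted p = 0.544), and none of the 14 had an unadjusted p under 0.05. Cxcl12 was at -0.21 ± 0.29 and its signalling receptor Cxcr4 at 0.17 ± 0.30. Vcam1 was at 0.79 ± 0.34, Cxcr3 at -0.79 ± 0.41 and Ccrl2 at 0.65 ± 0.40. BMP and TGF-beta genes had a median of -0.14 (30 genes, 3 lower at an unadjusted p under 0.05, adjusted p = 0.0873). Tgfb1 was at -1.22 ± 0.41 with its other kept probe set at 0.10 ± 0.50, Tgfb3 at -0.67 ± 0.28 and the BMP signal transducer Smad1 at -0.59 ± 0.23. Notch genes had a median of -0.07 (17 genes, none at an unadjusted p under 0.05, adjusted p = 0.925), with Hes1 at 0.51 ± 0.29, Notch1 at -0.40 ± 0.28 and Notch3 at -0.40 ± 0.28. Wnt genes had a median of 0.08 (26 genes, adjusted p = 0.541), and Wif1 rose adjusted over the list alone.

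Valve transcription factors (24 genes, median -0.10), hypoxia and glycolysis genes (27 genes, median 0.06) and the chromosome 1 neighbours of Cxcr7 (33 genes, median -0.03, or 0.026 after median centring and 0.063 after quantile normalization) did not pass, each at adjusted p = 0.925. Immediate early genes, a sign of dissection stress, had a median of -0.04 (31 genes, or 0.016 after median centring, adjusted p = 0.666). The list test pointed up where the median was negative for metalloproteinases, shear-responsive genes, cartilage genes and the chromosome 1 neighbours, and the mean of the hypoxia genes was -0.10. In all, 7 of 27 lists passed with the preset correlation, 4 higher and 3 lower, and none passed with an estimated correlation or by fry in 1 direction (smallest adjusted p = 0.210). Fry's test for change in either direction passed 3 lists, the cell cycle, collagen and elastic fibre, and ADAMTS and proteoglycan genes.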

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

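The tests of explanations in this part were chosen after the results were seen. Of the 64 control probe sets of the array, which entered no comparison, 13 had higher signal in both Cxcr7-/- pools than in both control pools and 6 had lower signal in both, together 29.7%, where chance gives 33.3%. The ratio of mean Cxcr7-/- to mean control signal was 1.92, 2.22 and 1.70 for the 3', 5' and middle probe sets of 18S ribosomal RNA. It was 1.21, 1.80 and 1.42 for the 3', 5' and middle probe sets of Actb. For Gapdh it was 1.74 at the 5' end, 1.31 in the middle and 0.99 at the 3' end, where the genotypes overlapped. For the 3' probe set of pyruvate carboxylase it was 1.26. The 5' probe set of the dap spike was at 2.43, with 381 and 374 against 290 in control replicate 1 and 21.2 in control replicate 2, which carries most of the ratio. The 3' and middle probe sets of the transferrin receptor were at 2.02 and 3.68 and the middle probe set of the bioB control at 13.9, the last 3 at low signal. Among the 6 lower probe sets, MURINE_b1 was at 0.52 (3778 and 3200 against 6120 and 7354), MUR_b2 at 0.72 and a middle one of pyruvate carboxylase at 0.52. The 3', 5' and middle probe sets of another bioB set were at 0.81, 0.15 and 0.39, all at low signal. Probe sets of 1 transcript are not independent.

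Cell cycle and macrophage genes were higher in Cxcr7-/- pools, with medians of 0.67 and 0.71. A smaller share of myocardium would raise every other cell type alike. The lower of these medians exceeded the higher of the endothelial and collagen medians by 0.69 log2, so these lists did not rise alike in the 4 pools. A permutation over member genes gave p = 1e-05 for each of the 4 comparisons, the smallest that 100000 resamples can give. The lists were compared after their medians were seen, so this p was bound to be small. It measures no spread between pools and adds no evidence. Genes of a list are not independent replicates. The sex makeup of the pools stays open: Cxcr7-/- replicate 2 and control replicate 1, both with low Eif2s3y signal (52.4 and 104), differed by 0.60 in cell cycle genes and 0.46 in macrophage markers, but this is 1 pool per genotype, and macrophage markers differed by 0.39 between the control pools. RNA quality cannot be told apart from genotype, since the highest Actb 3' to 5' ratio of the Cxcr7-/- pools, 15.5, lay below the lowest of the control pools, 19.1, and more proliferating cells and macrophages in the mutant leaflets may stand beside it as an open hypothesis.

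Cardiomyocyte markers were lower in Cxcr7-/- pools, with a median of -0.88. Without control replicate 2 the median was -0.51, but this rests on a lone control pool. Cxcr7-/- replicate 2 and control replicate 1 differed by a median of -0.16, with 9 of 29 genes higher in the Cxcr7-/- pool. A deviating pool can therefore not be told apart from genotype here. Pool-to-pool variation in the myocardium carried with the leaflets is a candidate explanation: the control pools differed from each other by 0.97 log2. That is a difference between single pools, which varies more than the genotype difference between means of 2 pools. The 2 sizes are therefore not on 1 scale. A genotype effect on muscle content stays open and was not tested apart from pool-to-pool variation.

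Secretoglobin genes had higher signal in the control pools, with a median log2 fold change of -2.37. Lung or airway tissue carried into those pools may be the source, but the 13 other measured airway genes had a median of -0.25 (SD 0.47, 10 lower). Of these, 2 had a control mean signal of at least 500. Abca3 was at -0.65 ± 0.28. Sftpc read 105 and 622 in the Cxcr7-/- pools against 477 and 665, so the genotypes overlapped. Of 9 further airway genes below the signal filter 6 were lower (median -0.50), among them Ager, at 9.19 and 55.6 against 146 and 312, and Sftpa1 at -1.73 and Sftpd at -1.03, while Nkx2-1 was at 0.42. With so few bright genes, carried tissue cannot be told apart from another origin of the secretoglobin signal. No biological explanation was tested.

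The 4 arrays can be parted into equal groups in 3 ways, too few for a share under 0.05. The real parting gave 240 probe sets at least 2-fold apart in all cross comparisons, as the 1 parting with so many, with 66 higher and 174 lower in Cxcr7-/- pools, and the highest of the others gave 186, with 12 and 174, for Cxcr7-/- replicate 1 with control replicate 2 against the other arrays. That parting had 1 probe set past the adjusted threshold, where genotype had 0. By the preset correlation 7 lists passed for genotype, 5 for both replicates 1 against both replicates 2 and 4 for the remaining parting. Between replicates 1 and 2, cardiomyocyte markers had a median of -0.75 (adjusted p = 3.73e-17, smaller than for genotype), smooth muscle markers -0.24 (0.0204) and macrophage markers 0.28 (0.0184). With an estimated correlation the adjusted p was 0.744, 0.744 and 0.786.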

How the results depend on the processing

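The crossed pairing and the adjustments over fewer probe sets were chosen after seeing the data. The absence of probe sets past the adjusted threshold in limma held under other pseudocounts, filters, normalizations and variance models, at adjusted p under 0.10, and with 1 probe set per gene, beside 2279 at an unadjusted p under 0.05. It was 0 with the replicate number as a block and 5 with the crossed pairing. Adjusted over the 536 genes of the lists alone, 3 passed: Cldn5, Hbegf and Mrc1 (each at adjusted p = 0.0451). With arrays left out it ranged from 0 to 673, with 8 without Cxcr7-/- replicate 2 and 673 without control replicate 1. The log2 fold change of Cxcr7 was -5.78 with no pseudocount and -4.61 with one 4 times larger, ranged from -6.73 to -3.93 with arrays left out, and passed without Cxcr7-/- replicate 2 and without control replicate 1. The 240 probe sets at least 2-fold apart in all cross comparisons became 365 with no pseudocount, 90 with one 4 times larger, 829 with no filter, 65 with the filter at the 75th percentile, 1295 at 1.5-fold, and 698 to 1705 with an array left out, where fewer arrays must agree.

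The 7 lists that passed were 0 with an estimated correlation and 0 by fry in 1 direction, and 5 to 10 lists passed under the other settings run, arrays left out included. Their medians are the same under these tests: -0.88 for cardiomyocyte, -0.57 for smooth muscle, -0.89 for adipocyte, 0.67 for cell cycle, 0.71 for macrophage, 0.55 for interferon and 0.44 for neuronal lists. The adjusted p was 0.713 for each with an estimated correlation and from 0.210 to 0.546 by fry. The shared 0.713 comes from the adjustment. Before it, camera with an estimated correlation gave p from 0.0371 for cell cycle genes to 0.185 for interferon genes, with 0.179 for cardiomyocyte markers. The estimated correlation was 0.064 for cell cycle genes and 0.72 for cardiomyocyte markers. With arrays left out, the interferon median ranged from 0.28 to 0.68 and did not pass without Cxcr7-/- replicate 1, and the neuronal median ranged from 0.23 to 0.57 and did not pass without Cxcr7-/- replicate 2 or control replicate 1. The cause was not tested.

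Of the lists that did not pass, several medians near 0 changed sign, and the cause was not tested. With the mean of all probe sets of a gene, the ADAMTS list was at -0.033 and immediate early genes at 0.11. Without a filter, the chromosome 1 neighbours were at 0.052. With the filter at the 75th percentile they were at 0.14, the CXCL12 list at -0.044 and cartilage genes at 0.030. Quantile normalization put the neighbours at 0.063, and median centring put them at 0.026, collagens at 0.024 and immediate early genes at 0.016. Of 65 named genes, only Plin4 changed sign, at -2.15 to 0.37 with arrays left out. Some named genes passed the adjusted threshold with an array left out, where 1 genotype rests on a lone array. Among named genes that passed adjusted over their list alone, this occurred in the leave-outs only without control replicate 1. The same leave-outs gave ranges of -0.041 to 0.24 for the ADAMTS list, -0.10 to 0.044 for metalloproteinases, -0.039 to 0.090 for Notch genes, -0.088 to 0.17 for shear-responsive genes, -0.17 to 0.048 for valve transcription factors and -0.24 to 0.086 for cartilage genes. They gave -0.72 to 0.012 for erythroid markers, -1.10 to 0.38 for neutrophil and mast cell markers, -0.33 to 0.57 for melanocyte markers, -0.18 to 0.027 for immediate early genes, -0.13 to 0.20 for hypoxia genes and -0.037 to 0.11 for the chromosome 1 neighbours. Melanocyte markers passed at -0.33 without Cxcr7-/- replicate 1 and at 0.57 without Cxcr7-/- replicate 2. In 12 fits, the last included, a list that had not passed did so with the same sign: neutrophil and mast cell markers at -0.94 without Cxcr7-/- replicate 2 and -1.10 without control replicate 2, erythroid markers at -0.53, ERK genes at 0.29, endothelial markers at -0.11, the ADAMTS list at 0.24 and hypoxia genes at 0.20, each without 1 array, and collagens and BMP and TGF-beta genes without 1 array and after quantile normalization. How far signal over background limits these counts was not tested.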

Other observations

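The gene lists, genes and other partings of the arrays in this part were chosen after the values were seen. Genes of antigen presentation by MHC class II were looked up because H2-Eb1 was among the named genes, so no test is given for them. The 5 measured genes, H2-Eb1 included, had positive log2 fold changes with a median of 1.24. Of 4 genes below the signal filter, H2-DMb2 was at 0.52, Ciita at -0.14, H2-Oa at -0.66 and H2-Ea at -0.76. H2-Aa read 2341 and 1937 against 863 and 909, a log2 fold change of 1.24 ± 0.26, and H2-DMa was at 1.47 ± 0.42, while the invariant chain gene Cd74 was at 0.29 ± 0.45. Macrophage markers were higher in the same pools (median 0.71), and a link between the 2 was not tested. Fatty acid oxidation genes, among them the already named Lpl, had a median of -0.30 with 16 of 19 negative, and no test is given for the same reason. Pdk4, which restrains glucose oxidation, was at -1.76 ± 0.50 and the fatty acid carrier gene Fabp3 at -1.20 ± 0.30. Pdk4 read 228 and 357 against 595 and 1734, the last in control replicate 2, which weighs on its fold change. Oxidative phosphorylation genes had a median of -0.19, with 33 of 40 negative, but the control pools differed from each other by a median of 0.42. The latter compares single pools and the former means of 2 pools, so the sizes are not on 1 scale. No test is given for these genes either, since the list was made after the lower heart muscle genes were seen. These metabolic genes are abundant in heart muscle, and the cardiomyocyte markers were lower in the same pools. Lung and airway genes had a median of -0.37 with 13 of 16 negative, and of -0.25 without the 3 secretoglobins for which the list was made. Arterial endothelial genes had a median of 0.04 (19 genes, adjusted p = 0.868), although Gja4 was at -1.48 ± 0.26 and the arterial ligand gene Efnb2 at -0.67 ± 0.24.

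Adm, which encodes adrenomedullin, a vasoactive peptide that Cxcr7 is known to bind, read 67.3 and 412 in the Cxcr7-/- pools and 7350 and 1083 in the control pools. Its log2 fold change was -3.86 ± 0.94 (adjusted p = 0.406), and its other kept probe set was at -1.84 ± 0.59. Calcrl, which encodes the adrenomedullin receptor, read 7276 and 7752 against 5737 and 3120, a log2 fold change of 0.82 ± 0.31 on which control replicate 2 weighs. Its partners Ramp2 and Ramp3 were at 0.17 ± 0.28 and -0.28 ± 0.31. The 5 measured genes of this system had a median of -0.28 (adjusted p = 0.474). The forkhead factor gene Foxc2 read 464 and 629 against 1178 and 1363 (-1.20 ± 0.29).

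Markers of some blood and pigment cells varied between pools without following genotype. Neutrophil and mast cell genes were low in Cxcr7-/- replicate 1 and control replicate 2 and higher in the other pools: Ngp read 92.5 and 643 in the Cxcr7-/- pools and 732 and 154 in the control pools, S100a8 read 234 and 630 against 852 and 252, and the mast cell protease gene Cpa3 read 30.1 and 538 against 831 and 202. Relative to each gene's mean, the list's median was -0.81, 0.55, 0.89 and -0.42 in Cxcr7-/- replicates 1 and 2 and control replicates 1 and 2. Melanocyte genes were higher where these were low, with 0.42, -0.40, -0.24 and 0.14, and the pigment enzyme gene Dct read 8994 and 3969 against 4385 and 7129. Xist read 4.18 in Cxcr7-/- replicate 1 and 17027, 25827 and 13853 in Cxcr7-/- replicate 2, control replicate 1 and control replicate 2. The Y-linked gene Eif2s3y read 3288, 52.4, 104 and 809 in the same order. The lymphocyte gene Rag1 read 35.4, 977, 143 and 112 in that order.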
